A study of Mus musculus with 22 samples.

How the data were processed

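RNA sequencing of mouse embryonic stem (ES) cells was deposited as 1 gene table for each of 22 libraries. The untreated set holds 10 libraries: 3 titled E14-chen (called E14 here, after the mouse ES cell line), 3 Dux-KO clones numbered 15, 22 and 52, and 4 Dux n=1 clones (titled Duxnto1) numbered 17, 22, 31 and 40. Both kinds of edited cells were made by CRISPR-Cas9, per the labels, and their names are read here as no Dux and 1 Dux copy. The treated set holds 12 libraries, 2 for each combination of 3 genotypes (WT, KO22 and N22) with DMSO or GSK-3484862, a degrader of the maintenance DNA methyltransferase DNMT1, given for 3 days. KO22 and N22 (titled Dux-KO22 and Dux-N22) are read as 1 clone each, so that genotype and clone are not separated in this set. The treatment protocol gives the dose as 1 uM and the design text of the series as 2 uM, so the dose is uncertain. Groups and clone numbers were taken from sample titles. The titles give no culture, day or batch, so that p-values measure only the spread between these samples, which may be technical within a line or clone.

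Cells were grown in serum and LIF, and 1 ug of total RNA entered a VAHTS Universal V6 library kit, per the labels' protocols. Reads were trimmed with fastp 0.23.2, aligned with HISAT2 2.1.0 to GRCm38 and counted with featureCounts 2.0.1, and DESeq2 1.40.2 is listed as well, per the submitters' processing notes. The deposited values are raw counts of fragments over exons per gene of the Ensembl 84 annotation, not normalized, per the file headers. The recorded counting commands ask for paired reads (22 of 22 files) and for neither multi-mapping reads nor strand (0 of 22 each). Fragments from near-identical copies, such as Dux, Zscan4, Usp17l, Tdpoz, Xlr and Magea genes, are therefore partly lost or assigned to 1 copy, and values of single members are uncertain. Overlapping and antisense genes cannot be told apart without strand. Symbols came from GENCODE M21, which matched 47310 of 47729 identifiers. All 22 tables had a sample and a named gene in every row.

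Total counts ranged from 15803194 to 19427794 per library. Counting intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. A group with no counts was given a floor of 3 counts over the group, and a fold against it is written as a lower bound. For a group with 1 to 3 counts the ratio carries an exact 95% interval. Libraries of 1 group differed by more than sampling noise in every pair (chi-square per degree of freedom 2.72 to 58.5), and no 2 libraries held identical values.

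Each set was fitted in 1 model with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with a minimum count of 10, robust quasi-likelihood test), without a replicate term. The untreated fit tested 14796 genes (common biological coefficient of variation 0.208) and the treated fit 16641 (0.0435). A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The 15 comparisons were Dux-KO, Dux n=1 and E14 against each other, the response to GSK-3484862 within each genotype, the differences between these responses as interaction contrasts, and the genotypes against each other within DMSO and within GSK-3484862. Fold changes are log2 with the standard error (SE).

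Before the data were examined, 13 gene lists, the main test, most alternatives and the rule for named genes were fixed. The lists are the Dux family, genes of the 2-cell embryo, pluripotency, germline, X-linked testis and placenta genes, imprinted genes, the DNA methylation machinery, trophoblast, primitive endoderm, primed and germ layer genes, fibroblasts (feeder cells), p53 targets and the interferon response. Of 317 list genes, 314 were found. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01), with an estimated correlation and fry as alternatives, adjusted over the lists of a comparison. The Dux family had too few tested members for a list test and is given as counts. Adjusted p-values of lists are from limma camera and those of genes from edgeR. The rule named Dux and 7 fixed 2-cell genes, then the 10 largest called changes in each direction with a mean log2 CPM of at least 1 and no overlap between groups, then up to 3 members of each list with the smallest p. Unnamed gene models and pseudogenes were left out of the largest changes. Genes with 3 or fewer counts in a group were, after their values were seen, given as counts or left unnamed, and fewer genes are named than the rule allows. The summed CPM (counts scaled to the library total) of the 2-cell list were compared between untreated groups by an exact permutation test.

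Alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, only the compared groups in the fit, a replicate block in the treated set, 2-cell lists without multi-copy families, and each library left out in turn. Where this left 1 library in a group, it was assumed to vary like those of the other groups. A per-library GC content offset, omission of 2 doubted libraries and omission of chromosome 6 were added after the data were examined. The tests were checked on simulated counts with 200 changed genes. For Dux-KO against E14 (14563 genes), 65% of 2-fold and 88% of 4-fold changes were recovered. For GSK-3484862 in WT (16060 genes), 77% and 92% were recovered. With a GC content trend added to the simulated counts and no offset, 32% of 2-fold changes were recovered for Dux-KO against E14 and 63.9% of calls were false, and for GSK-3484862 in WT 97.9% of calls were false. With the GC content offset the false share was 6.4% and 7.7%, and the plain simulations gave 6.7% and 8.6%. The added trend gave rank correlations of fold change with GC content of 0.84 and 0.93 without an offset. In the treated libraries, the deviation from WT with DMSO correlated with GC content at -0.20 to 0.20. In WT the compound changed 9456 genes, far more than were simulated. For Dux-KO against E14, 3016 genes were called, also far more than simulated. The deviation of the Dux-KO libraries from E14 correlated with GC content at 0.47 to 0.69. These simulations therefore do not give error rates of the real data in either set.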

Results

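The study asks whether the duplicated Dux cluster is needed for full expression of genes of the 2-cell embryo, in untreated mouse ES cells and with a compound given to lower DNA methylation. Dux encodes a double homeobox transcription factor that activates 2-cell embryo genes. Gene counts were analysed in 22 libraries. The untreated set has 3 E14, 3 Dux-KO and 4 Dux n=1 libraries, and the treated set has 2 libraries for each of WT, KO22 and N22 with DMSO and with GSK-3484862. Depth ranged from 15803194 counts (Dux n=1 clone 31) to 19427794 (WT DMSO 2). The share of counts on mitochondrial genes was 1.66% to 2.39% in the 6 DMSO libraries and 2.66% to 3.20% in the 6 libraries given GSK-3484862. It was 2.75% to 2.99% in E14 and lower, at 2.03% to 2.60%, in all 7 edited untreated libraries. With DMSO the order was the reverse, at 1.78% and 1.66% in WT and 2.17% to 2.39% in KO22 and N22.

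Dux itself was counted first in every library. Duxf3 (ENSMUSG00000075046, the annotated Dux gene, GRCm38 chromosome 10, 58229979 to 58232675) had 1, 0 and 0 counts in the E14 libraries. Among the Dux-KO libraries it had 0 counts in clone 15, 1 in clone 52 and 5 in the library labelled Dux-KO clone 22. The Dux n=1 clones 17, 22, 31 and 40 had 1, 3, 0 and 1 counts. In the treated set, Duxf3 had 0 counts in all 4 KO22 libraries, a count that allows up to 0.155 to 0.167 CPM per library. WT had 1 and 1 counts with DMSO and 19 and 18 with GSK-3484862, and N22 had 3 and 0, then 13 and 11. The neighbouring copy Gm4981 (58234848 to 58236701) had 5 and 4 counts in WT and 7 and 1 in N22 with GSK-3484862. Elsewhere it had 1 count, in E14 library 3. Of the related Duxbl genes on chromosome 14, Duxbl2 had 9 and 11 counts in WT with GSK-3484862 and at most 2 in any other library, Duxbl1 had at most 2, and Duxbl3 had 0 in all 22. Reads shared between Dux copies were not counted, so these numbers do not measure copy number.

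Zscan4, a family of genes of the 2-cell embryo that also marks rare ES cells in that state, was counted next. Its 5 members summed to 92, 92 and 86 counts in E14. Dux-KO clones 15 and 52 had 5 and 22, and the library labelled Dux-KO clone 22 had 49. Dux n=1 clones 17, 22, 31 and 40 had 38, 51, 12 and 5. KO22 had 0 and 0 counts with DMSO and 0 and 1 with GSK-3484862. N22 went from 38 and 47 to 410 and 411, and WT from 90 and 115 to 1114 and 1063.

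**Figure D1:**
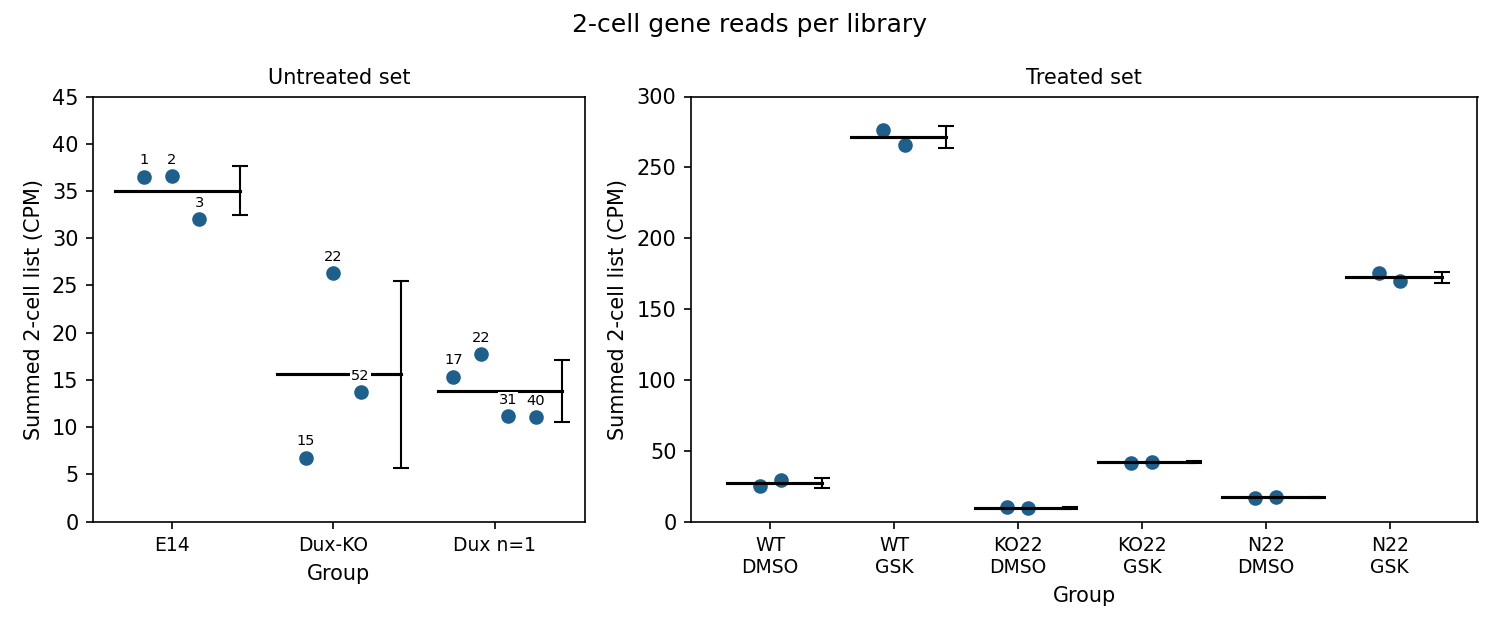
Summed CPM of the 2-cell gene list per library (points) by group, with the group mean (line) and SD (bar); clone or replicate numbers stand over the untreated points, and the vertical scales of the panels differ. WT and N22 with GSK-3484862 averaged 271 and 172 CPM, against 42.0 CPM in KO22.

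Summed over the 2-cell list, reads came to 35.0 ± 2.60 CPM in E14 (SD, n = 3), 15.6 ± 9.91 in Dux-KO (SD, n = 3) and 13.8 ± 3.28 in Dux n=1 (SD, n = 4). Every edited library lay below every E14 library in this sum. Without multi-copy families the library labelled Dux-KO clone 22 (13.9 CPM) lay above E14 libraries 1 and 3 (13.8 and 12.4), and the log2 difference of Dux-KO from E14 was -0.74 instead of -1.38, and that of Dux n=1 -0.80 instead of -1.37. The library labelled Dux-KO clone 22 was the highest of the edited ones at 26.3 CPM. In two-sided exact permutation tests of log2 CPM, Dux n=1 against E14 gave p = 0.0286 (adjusted over 3 comparisons 0.0857) and Dux-KO against E14 gave p = 0.1 (adjusted 0.15). Each is the smallest p its design allows. Dux n=1 against Dux-KO gave an exact p = 1.

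Dux-KO against E14 asks what loss of Dux does in untreated cells, although line and clone differences are not separated from it. Stra8, the retinoic acid response gene of meiotic entry, rose by 4.01 ± 0.79 (log2, SE), and Aurkc, a meiotic kinase, by 4.58 ± 1.34, while the germline list was not called. Rhobtb1 (4.30), Ndufa4l2 (3.98) and Ptges, a prostaglandin E synthase (3.05), also rose. In KO22 against WT with DMSO, Stra8 (408 counts against 1347) and Ndufa4l2 (82 against 1030) went the other way. Rian (7 counts against 604) was lower in both comparisons. Id2, an inhibitor of bHLH factors, fell by 2.67 ± 0.54, and Kitl (the KIT ligand), Vgll3 and Coch fell by 2.62, 2.46 and 2.38. Of the 2-cell list, 2 of 13 tested members fell, 0 rose and 11 were not called (4 fell when adjusted over the list alone). The fallen members were Gm21761 (-2.32, adjusted p = 0.0342) and Ddit4l (-0.92, adjusted p = 0.039), and the list had a median of -1.64 (adjusted p = 0.0014; adjusted p = 0.548 with an estimated correlation). Without multi-copy families the median was -0.47 and not called (adjusted p = 0.407). Zscan4c, Zscan4d and Usp17la had log2 differences of -1.93, -1.96 and -1.23 that did not pass (adjusted p = 0.159, 0.0626 and 0.278). Without the library labelled Dux-KO clone 22, Zscan4c passed (-3.46, adjusted p = 0.0423), and Zscan4d passed with DESeq2 (adjusted p = 0.0403). Imprinted genes fell in 6 of 25 cases and rose in 0 (list alone 6), among them Igf2 (-1.93), Grb10 (-0.64) and Rian (-3.71; 5 counts against 65). The list's median was -0.54 (adjusted p = 0.0014; adjusted p = 0.113 with an estimated correlation). Among 21 p53 targets 7 fell and 1 rose (list alone 8 and 1), with Perp at -1.66, Ccng1 at -1.11 and Trp53inp1 at -1.21. The median was -0.36 (adjusted p = 0.002; adjusted p = 0.548 with an estimated correlation). The de novo methyltransferase Dnmt3a rose by 0.97 ± 0.14 and Tet1, a 5-methylcytosine oxidase, fell by 0.95 ± 0.18. Eomes (1.13), Thy1 (1.96) and Utf1 (0.78) rose. The germline list had a median of 0.52, with 4 of 27 higher and 1 lower (list alone 6 and 2; adjusted p = 0.159), and passed with a GC content offset (0.00048) and without the library labelled Dux-KO clone 22 (0.0431).

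By edgeR, 3016 of 14796 genes were called for Dux-KO against E14, 1370 higher and 1646 lower. With a GC content offset 973 were called, 545 higher and 428 lower, and Gm21761, Ddit4l, Aurkc, Ndufa4l2, Kitl, Rian, Trp53inp1 and Utf1 were no longer called (adjusted p = 0.0658 to 0.215). With the offset the log2 differences were -2.27 for Gm21761, -0.80 for Ddit4l, 4.48 for Aurkc, 3.58 for Ndufa4l2, -2.08 for Kitl and -2.95 for Rian, while those of Trp53inp1 (-0.60) and Utf1 (0.32) shrank by more than 1.5 times. Without E14 library 1, 2 or 3 there were 931, 1739 and 1171 calls, and without Dux-KO clone 15 there were 1977. Without any 1 E14 library, Gm21761, Ddit4l, Aurkc, Ndufa4l2 and Kitl lost the call (adjusted p = 0.0562 to 0.121), as did Grb10, Utf1 and Rian without E14 library 1 (adjusted p = 0.0645, 0.0502 and 0.05). Gm21761 and Ddit4l also lost it without Dux-KO clone 15 (adjusted p = 0.0759 and 0.109) or 52 (0.108 and 0.0959). Aurkc (0.123) and Ndufa4l2 (0.101) lost it without clone 15, and Kitl (0.0615) and Rian (0.0523) without clone 52. Chromosome 6 genes were higher as a set, with a median of 0.20 against 0.01 elsewhere, and 87 of 689 were called higher and 23 lower.

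Dux n=1 against E14 asks what remains with 1 Dux copy, again without separating line and clone differences. Of the 2-cell list, 3 of 13 tested members fell, 0 rose and 10 were not called (9 fell when adjusted over the list alone). Gm21761 fell by 2.40 ± 0.62 and Ddit4l by 0.92 ± 0.26. The list's median was -1.78 (adjusted p = 2.12e-05; adjusted p = 0.448 with an estimated correlation). Without multi-copy families the median was -0.68 and not called (adjusted p = 0.406). Zscan4c (-1.62), Zscan4d (-1.78) and Usp17la (-1.56) did not pass (adjusted p = 0.22, 0.087 and 0.18). Rhobtb1 (2.87), Stra8 (2.85) and the myeloid kinase gene Fgr (2.28) rose. The small RNAs Rn7sk (-7.56) and Rpph1 (-6.45) were called lower, but E14 was uneven. Rn7sk had 51.1 and 66.6 CPM in E14 libraries 1 and 3 and 1.81 in library 2, against at most 0.316 in Dux n=1. Coch (-2.45), the heart factor Tbx20 (-2.14) and Id2 (-2.02) fell. Of 25 imprinted genes 3 fell and 0 rose (list alone 4), including Igf2 (-1.45) and Impact (-0.87). Their median was -0.41 (adjusted p = 0.0038; adjusted p = 0.188 with an estimated correlation). Of 21 p53 targets 7 fell and 0 rose (list alone 10), with Perp at -2.01, Plk2 at -1.17 and Ccng1 at -1.14. Their median was -0.35 (adjusted p = 0.000105; adjusted p = 0.448 with an estimated correlation). Dnmt3a rose by 1.15 ± 0.13 and Uhrf1, the partner of DNMT1, by 0.35 ± 0.09.

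By edgeR, 1355 of 14796 genes were called for Dux n=1 against E14, 722 higher and 633 lower, and DESeq2 called 2515. There were 24, 344 and 52 calls without E14 library 1, 2 and 3, and 351 without Dux n=1 clone 17. With a GC content offset 328 were called, and Gm21761, Ddit4l, Rhobtb1, Stra8, Tbx20, Id2, Impact and Uhrf1 lost the call (adjusted p = 0.0543 to 0.184). Their log2 differences were then -2.36, -0.83, 2.77, 2.81, -1.88, -1.89, -0.61 and 0.21, of which that of Uhrf1 shrank by more than 1.5 times. With only the compared groups in the fit 2450 were called. Of the 22 genes considered for naming here, 15 lost the call in at least 1 omission. Without E14 library 1, 2 or 3 the call was lost by 15, 12 and 14 of them, and without Dux n=1 clone 17, 22, 31 or 40 by 11, 4, 5 and 4 (adjusted p = 0.0505 to 0.189 over all omissions). Coch, Perp, Ccng1 and Dnmt3a kept theirs in every omission, and Zscan4c, Zscan4d and Usp17la had none to lose.

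No gene was called between Dux n=1 and Dux-KO by edgeR, with 856 genes at an unadjusted p below 0.05, and DESeq2 also called 0. Zscan4c (0.31 ± 0.92), Zscan4d (0.18 ± 0.69) and Usp17la (-0.33 ± 0.79) were not called. None of the 12 lists passed, and the 2-cell list had a median of -0.24 (adjusted p = 0.509), with 0 of 13 members called over all genes or adjusted over the list alone. This direction changed with single libraries. Without the library labelled Dux-KO clone 22 the 2-cell median was 0.52 (adjusted p = 0.175), it was 0.08 without Dux n=1 clone 40 and -0.65 without Dux-KO clone 15 (adjusted p = 0.000203). Zscan4c and Zscan4d turned negative without Dux-KO clone 15 (-0.28 and -0.30) or without Dux n=1 clone 17 (-0.06 and -0.06) or 22 (-0.06 and -0.27), and Usp17la turned positive without clone 31 (0.04) or 40 (0.03). The germline list (median -0.18, adjusted p = 0.0801) passed with a GC content offset (0.000566) or no count filter (0.0341), and without the library labelled Dux-KO clone 22 (0.0055) or Dux n=1 clone 17 (0.0197) or 31 (0.0413), and its median was 0.04 (0.38) without Dux-KO clone 15. The X-linked list (-0.73, adjusted p = 0.166) passed without Dux-KO clone 52 (0.0161) or Dux n=1 clone 17 (0.0197), and its median was 0.23 (0.789) with no count filter. With the library labelled Dux-KO clone 22 and Dux n=1 clone 40 both left out, a choice made after their 2-cell values were seen, 140 genes were called (52 higher and 88 lower), and the 2-cell median was 0.74 (adjusted p = 0.028).

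GSK-3484862 against DMSO in WT gives the response to this compound without editing of Dux; DNMT1 protein and DNA methylation were not analysed here. Of 38 tested 2-cell genes, 37 rose and 0 fell (list alone 37), with a median of 3.45 (adjusted p = 4.93e-16). Zscan4c rose by 3.54 ± 0.24 and Zscan4d by 3.31 ± 0.22, Zfp352, a 2-cell zinc finger gene, by 3.85, Tcstv3 by 3.29, Usp17la by 3.26 and Tmem92 by 4.08. Tmem92 lost the call with DESeq2 (adjusted p = 0.0621). Duxf3 went from 2 to 37 counts, a ratio of 19.5 (95% counting interval 5.02 to 167). Summed 2-cell reads went from 27.3 ± 3.27 to 271 ± 7.62 CPM (SD, n = 2), or 9.94-fold. All 20 X-linked testis and placenta genes rose (list alone 20; median 4.69, adjusted p = 4.27e-11), among them Rhox5, a reproductive homeobox gene (1.39 ± 0.08). Of 31 imprinted genes 23 rose and 5 fell (list alone 23 and 5; median 1.14, adjusted p = 7.96e-07), with the noncoding RNA H19 at 5.33, Mest at 4.89, Meg3 at 3.38, Rian at 3.27 and Peg13 at 5.97. Of 28 germline genes 17 rose and 5 fell (list alone the same counts; median 0.73, adjusted p = 0.000761). Fkbp6, needed for meiotic pairing, rose by 4.68, Stk31 by 2.38 and Tex19.1, a placenta and germ cell gene, by 1.63.

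Of 21 p53 targets in WT 17 rose and 1 fell (list alone 17 and 1; median 0.72, adjusted p = 2.03e-08), including the p53 ligase Mdm2 (1.39 ± 0.04), Plk2 (2.25) and the apoptosis effector Perp (2.64). Of 22 pluripotency genes 16 fell and 3 rose (list alone 16 and 3; median -0.44, adjusted p = 6.76e-05), among them Tdgf1 (-0.84), Tfcp2l1 (-0.81) and Dppa5a (-0.60). Primitive endoderm genes rose in 13 of 18 cases and fell in 2 (list alone 13 and 2), with the basement membrane genes Col4a1 at 1.35 and Sparc at 0.77. Their median was 1.33 (adjusted p = 0.000271; adjusted p = 0.0847 with an estimated correlation). Dnmt3l rose (1.51) and Tet1 fell (-0.55), while the DNA methylation machinery as a list was not called (9 of 21 rose and 6 fell; adjusted p = 0.728). Also not called were the trophoblast (7 of 17 rose and 1 fell; adjusted p = 0.193), primed and germ layer (8 of 17 and 4; 0.0805), fibroblast (6 of 11 and 3; 0.363) and interferon (4 of 13 and 1; 0.245) lists, with the same counts adjusted over the list alone except for 6 trophoblast genes higher. The primed and germ layer list passed without WT DMSO 1 (adjusted p = 0.0493) and with no count filter (0.0411). Their members Gata3 (2.14), Nodal (1.01) and Ddx58 (1.58) rose, and Fn1 (-1.05) and Stat2 (-1.27) fell. Cd200 rose by 5.61. The genes that fell most included Ndufa4l2 (-3.02), Bhlhe40 (-3.02), the glycolytic gene Aldoc (-2.87) and Loxl2 (-2.83). By edgeR, 9456 of 16641 genes were called in WT, 4776 higher and 4680 lower, of which 1982 and 817 by at least 2-fold.

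The same treatment in KO22, the line labelled as lacking Dux, gave no call for the 2-cell list as a whole. Of 38 members 6 rose, 0 fell and 32 were not called (list alone 4), with a median of 0.00 (adjusted p = 0.156). Ddit4l (2.23 ± 0.14), Zfp750 (1.91 ± 0.15) and Trim43b (2.85 ± 0.35) rose. Of the 2-cell counts in KO22 with GSK-3484862, 47.6% came from Ddit4l and 37.7% from Zfp750. Of the 38 members, 19 had 0 counts in all 4 KO22 libraries, so the median of 0.00 largely reflects members without a count. The sum went from 9.66 ± 0.50 to 42.0 ± 0.46 CPM (SD, n = 2), or 4.35-fold. Other groups rose: 19 of 20 X-linked genes (list alone 20; median 5.19, adjusted p = 1.65e-12), 24 of 31 imprinted genes with 3 lower (list alone 25 and 3; median 1.00, adjusted p = 8.24e-10) and 16 of 28 germline genes with 1 lower (list alone 16 and 1; median 0.54, adjusted p = 6.26e-05). Rhox5 rose by 2.56, Fkbp6 by 5.87, Stk31 by 2.19, Mest by 7.51, Rian by 9.50 and Meg3 by 9.87. The p53 targets rose in 19 of 21 cases and fell in 0 (list alone 20; median 1.10, adjusted p = 1.65e-12), with Mdm2 at 1.34, Plk2 at 1.98 and Perp at 2.44. Of 22 pluripotency genes 19 fell and 1 rose (list alone 19 and 1; median -0.30, adjusted p = 5.44e-09), with Tfcp2l1 at -1.01, Tbx3 at -0.96 and Tdh at -0.91. Primed and germ layer genes rose in 12 of 17 cases and fell in 2 (list alone 13 and 3; median 0.66, adjusted p = 0.0011), among them Pou3f1 (1.12) and Lefty2 (0.70). Primitive endoderm genes rose in 10 of 18 cases and fell in 2 (list alone 10 and 2), with a median of 0.74 (adjusted p = 0.0081; adjusted p = 0.178 with an estimated correlation). Trophoblast genes were not called as a list (9 of 17 higher and 2 lower, list alone 9 and 2; 1.06, adjusted p = 0.0565) but passed without KO22 DMSO 2 (0.0359) or KO22 GSK 1 (0.041) and with no count filter (0.0142). Pax8 (-3.14), Bdh2 (-2.72) and Slc38a5 (-2.31) fell most. By edgeR, 7656 genes were called, 4124 higher and 3532 lower.

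In N22, the line labelled as keeping 1 Dux copy, 36 of 38 2-cell genes rose and 0 fell (list alone 36), with a median of 3.69, or 3.41 with 9 members at their bounds (adjusted p = 4.43e-16). Zscan4c rose by 2.79 ± 0.28, Zscan4d by 3.40 ± 0.29, Usp17la by 4.69 ± 0.43 and Ddit4l by 3.09 ± 0.14. Duxf3 went from 3 to 24 counts, a ratio of 8.49 (95% counting interval 2.58 to 44.1), and its call was lost without N22 DMSO 2 (adjusted p = 0.11). The sum went from 17.0 ± 0.35 to 172 ± 3.90 CPM (SD, n = 2), or 10.1-fold. All 20 X-linked genes rose (list alone 20; median 4.72, adjusted p = 2.45e-12), as did 24 of 31 imprinted genes with 3 lower (list alone 24 and 3; median 1.28, adjusted p = 2.22e-09) and 18 of 28 germline genes with 5 lower (list alone 18 and 5; median 0.66, adjusted p = 0.000277). Rhox5 rose by 2.67, Fkbp6 by 4.93, H19 by 8.35, Mest by 7.60 and Rian by 10.21. In N22, 20 of 21 p53 targets rose and 0 fell (list alone 20; median 1.17, adjusted p = 5.5e-13), including Mdm2 (1.72), Plk2 (2.64) and Phlda3 (1.97). Of 22 pluripotency genes 17 fell and 1 rose (list alone 18 and 1; median -0.32, adjusted p = 1.08e-06), among them Tdgf1 (-0.84), Utf1 (-0.62) and Klf4 (-0.65). Primitive endoderm genes rose in 9 of 18 cases and fell in 2 (list alone 10 and 2), with a median of 1.31 (adjusted p = 0.0022; adjusted p = 0.144 with an estimated correlation). Loxl2 (-3.65), Ndufa4l2 (-3.45), A2m (-3.43), the oxygen sensor Egln3 (-2.90) and Aldoc (-2.57) fell. By edgeR, 8812 genes were called, 4481 higher and 4331 lower. Across 16641 genes, which are not independent replicates, fold changes in N22 and WT correlated at r = 0.82. Called genes were higher in both for 3479 (1286 for independent lists), lower in both for 3380 (1218) and opposite for 123. KO22 shared much of the response as well: with WT r was 0.67, with 2644 genes higher in both (1184 for independent lists), 2266 lower (993) and 637 opposite, and with N22 r was 0.72, with 2879 (1110), 2505 (919) and 247.

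The difference between the responses was tested directly. Responses are ranked by their signed log2 change with the compound. A lower one can thus be a smaller rise or a deeper fall. The 2-cell response in KO22 lay below that in WT, with a median difference of -3.25 over 38 members (adjusted p = 8.37e-20), while 2 members were lower singly, 0 higher and 36 not called (list alone 0). Of the 38, 19 had 0 counts in every KO22 library, and the fitted differences of such genes depend on the prior count. Among single genes, Bhlhe40 (3.27 ± 0.15) and Ndufa4l2 (2.43 ± 0.37) were lowered by the compound in WT, and their response in KO22 lay higher. Rian (6.23) and Mest (2.62) had larger responses in KO22, where their DMSO level was lower. The responses of Dnmt3l (-0.87), Tbx3 (-0.91), Tex19.1 (-0.74), Ccng1 (-0.43) and the RNA sensor gene Ddx58 (-1.16) lay lower in KO22, and those of Tdgf1 (0.65) and the apoptosis gene Bbc3 (1.12) higher. The primitive endoderm list (-0.33, adjusted p = 0.106) passed without WT DMSO 2 (0.0278). By edgeR, 5286 genes differed, 3042 with a higher response in KO22 and 2244 with a lower one.

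Between N22 and WT the 2-cell response was not found to differ. In N22 with DMSO, 9 of the 38 members given bounds above had 0 counts, and the fitted differences of such genes depend on the prior count. The median difference was 0.53 while camera gave the direction as down (adjusted p = 0.538), and the median was -0.01 without WT DMSO 2 (adjusted p = 0.171). Of 38 members 1 rose more in N22 (list alone 1): Gm21761, by 1.64 ± 0.39, whose call was lost without N22 DMSO 2 (adjusted p = 0.0619). Usp17la (1.42 ± 0.65), Zscan4c (-0.75 ± 0.42) and Zscan4d (0.09 ± 0.39) did not pass (adjusted p = 0.165, 0.294 and 0.93). Zscan4d turned negative without N22 DMSO 1 (-0.56), WT DMSO 2 (-0.22) or N22 GSK 2 (-0.12). The p53 targets responded more in N22, with 14 of 21 higher and 0 lower (list alone 14) and a median difference of 0.33 (adjusted p = 4.37e-09; adjusted p = 0.0056 with an estimated correlation). Among them were Bbc3 (0.65 ± 0.08), the cell cycle inhibitor Cdkn1a (0.63 ± 0.08) and Trp53inp1 (0.47 ± 0.06). Imprinted genes had a higher response in 8 of 31 cases and a lower one in 2 (list alone 8 and 3), with Rian at 6.95, H19 at 3.02 and Mest at 2.71 (median 0.20, adjusted p = 0.0031; adjusted p = 0.0771 with an estimated correlation). The DMSO levels of Rian, H19 and Mest were lower in N22 (0.106, 0.106 and 1.02 CPM) than in WT (15.7, 1.69 and 6.54). With GSK-3484862 they averaged 140, 38.4 and 206 CPM in N22 and 158, 71.1 and 203 in WT. Of the DNA methylation machinery 5 of 21 had a lower response and 1 a higher one (list alone 9 and 1), including Dppa2 (-0.52), Dnmt3b (-0.40) and the imprint protector Zfp57 (-0.39). The median was -0.11 (adjusted p = 0.0113; adjusted p = 0.0771 with an estimated correlation). Primed and germ layer genes had a lower response in 4 of 17 cases and a higher one in 1 (list alone 6 and 1), with Lefty2 at -0.45 (median -0.30, adjusted p = 0.0144; adjusted p = 0.0771 with an estimated correlation). By edgeR, 1844 genes differed, 968 higher and 876 lower, and DESeq2 called 1178.

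Against KO22, the 2-cell response of N22 lay higher by a median of 3.05 (adjusted p = 3.48e-24), with 2 of 38 members higher singly and 0 lower (list alone 2). The 19 members with 0 counts in every KO22 library enter with fitted values that depend on the prior count. The responses of the hyaluronan-binding gene Cemip (2.86), Il34 (2.76) and Ly6a (2.65) lay higher in N22. Those of the Wnt effector Lef1 (-3.25), Ndufa4l2 (-2.86), Bhlhe40 (-2.77) and Bnip3 (-2.53) lay lower. Ndufa4l2 went from 947 to 84 counts in N22, while KO22 had 82 counts already with DMSO. Of 21 p53 targets 9 responded more and 2 less (list alone 11 and 2; median 0.35, adjusted p = 0.000501), including Ccng1 (0.70), Phlda3 (0.64) and Trp53inp1 (0.58). Primed and germ layer genes had a lower response in 8 of 17 cases and a higher one in 1 (list alone 9 and 4), such as Zic2 (-1.47) and Lefty2 (-0.94). That list's median was -0.39 (adjusted p = 0.0489; adjusted p = 0.143 with an estimated correlation), and its call was lost without any 1 KO22 or N22 library (adjusted p = 0.128 to 0.245), with no count filter (0.192) and with a GC content offset (0.119). By edgeR, 3101 genes differed, 1300 higher and 1801 lower, and DESeq2 called 2047.

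**Figure D2:**
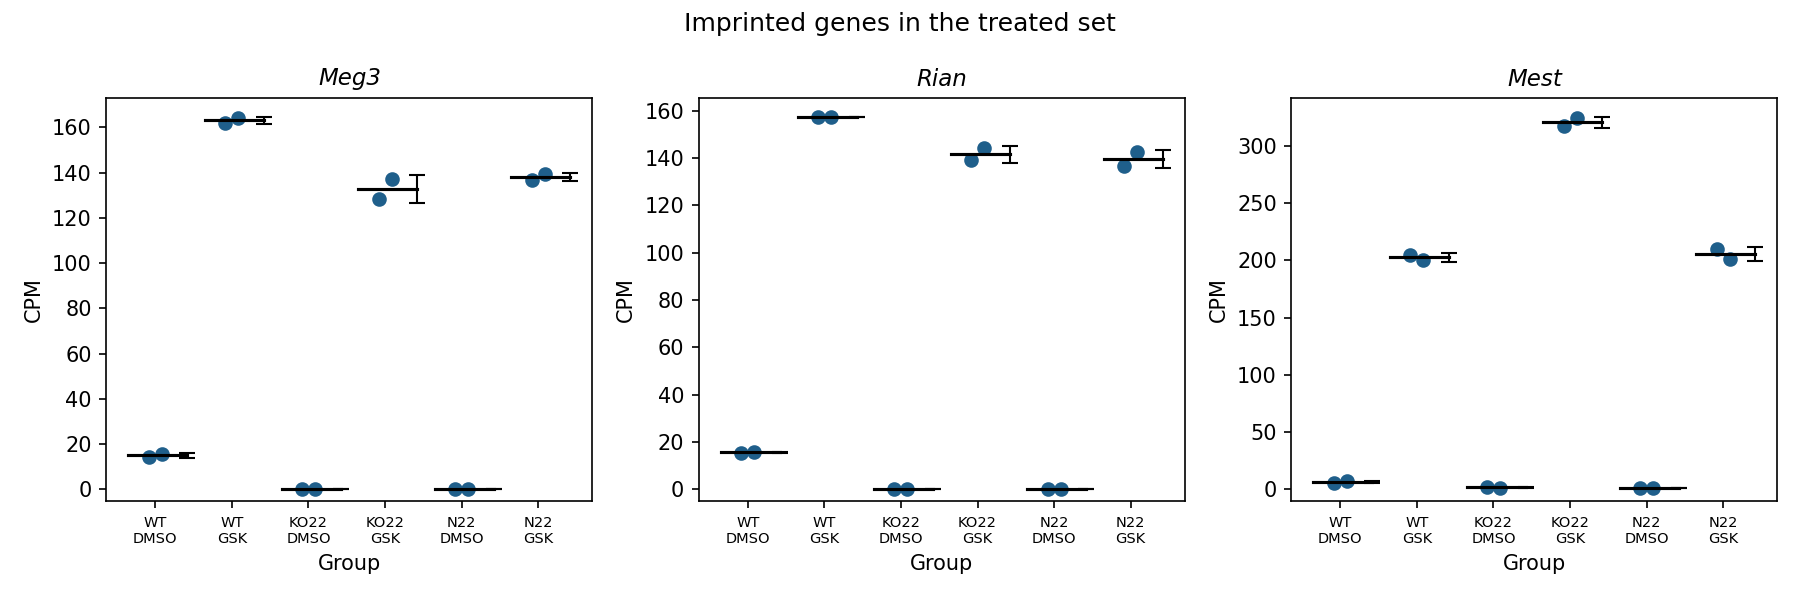
CPM of the imprinted genes Meg3, Rian and Mest in each library of the treated set (points), with the group mean (line) and SD (bar, n = 2). Meg3 averaged 15.0 CPM in WT with DMSO, 0.131 and 0.0528 in KO22 and N22 with DMSO, and 133 to 163 in the 3 groups given GSK-3484862.

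With DMSO alone, 2-cell genes were lower in KO22 than in WT. Of 38 2-cell genes 19 were lower and 0 higher (list alone 19), with a median of -4.06, or -2.16 with 21 members at their bounds (adjusted p = 6.51e-06). Without multi-copy families the median was -2.72 and not called (adjusted p = 0.506). Rian, an imprinted noncoding RNA (chromosome 12, 109603940 to 109661716), had 7 counts in KO22 and 604 in WT. As a list, imprinted genes were not called (13 of 31 lower and 7 higher, list alone the same counts; adjusted p = 0.506), and Peg10 was higher (1.03 ± 0.03). The pluripotency list (13 of 22 higher and 6 lower, list alone 13 and 6; median 0.16, adjusted p = 0.175) passed with no count filter (0.0384). The signalling inhibitor Lefty1 (-2.11), Zic2 (-1.69), the trophoblast factors Tfap2c (-1.98) and Fgfr2 (-2.62), and Stra8 (-1.69) were lower. Gpr83 (5.14), Nckap1l (3.27), the interferon-induced GTPase Irgm1 (3.10), Ddx58 (1.58), Tex19.1 (1.08), Dnmt3l (1.07) and Tbx3 (0.90) were higher. Rhox5 (-1.18), Tdgf1 (-0.57), Bbc3 (-1.06), Lamb1 (-1.32) and Fn1 (-0.61) were lower. By edgeR, 8643 genes were called, 3893 higher and 4750 lower. Of 805 chromosome 6 genes 340 were higher and 116 lower, with a median of 0.27 against -0.06 elsewhere.

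N22 against WT with DMSO gave 11 of 38 2-cell genes lower and 1 higher (list alone 12 and 1), with a median of -1.35, or -1.18 with 4 members at their bounds (adjusted p = 6.71e-05). Without multi-copy families the median was -1.40 and not called (adjusted p = 0.167). Gm21761 (-2.57 ± 0.35) and Usp17le (-1.55 ± 0.34) were lower. Usp17la (-2.28), Zscan4d (-1.36) and Zscan4e (-1.87) were lower too, and Zscan4c (-0.59) did not pass (adjusted p = 0.247). Usp17la lost the call without WT DMSO 1 (adjusted p = 0.0793), Zscan4d without N22 DMSO 1 (0.177) or WT DMSO 2 (0.0992), and Zscan4e without N22 DMSO 2 (0.103) or WT DMSO 2 (0.0534). Of 31 imprinted genes 13 were lower and 3 higher (list alone 14 and 4), with Rian at -7.11, H19 at -3.90 and Mest at -2.68. Their median was -0.27 (adjusted p = 0.0059; adjusted p = 0.0786 with an estimated correlation). Germline genes were lower in 8 of 28 cases and higher in 0 (list alone 8), with Stra8 at -0.73 and Mov10l1 at -0.62 (median -0.29, adjusted p = 0.0166; adjusted p = 0.0857 with an estimated correlation). Targets of p53 were lower in 9 of 21 cases and higher in 2 (list alone 11 and 2), such as Bbc3 (-0.46) and Cdkn1a (-0.40). Their median was -0.12 (adjusted p = 0.0233; adjusted p = 0.0786 with an estimated correlation), and the call was lost without N22 DMSO 1 (adjusted p = 0.0678). The DNA methylation machinery (9 of 21 higher and 3 lower, list alone 10 and 3; median 0.10, adjusted p = 0.0202) and primed and germ layer genes (6 of 17 and 2, list alone 7 and 2; 0.25, adjusted p = 0.0131) were higher, both with adjusted p = 0.0786 with an estimated correlation. Primitive endoderm genes were lower in 4 of 18 cases and higher in 1 (list alone 4 and 1; median -0.60, adjusted p = 0.048; adjusted p = 0.306 with an estimated correlation). That call was lost without N22 DMSO 1 (adjusted p = 0.0762) or WT DMSO 2 (0.175) and with a GC content offset (0.0683). Nlrc4 (2.37), Bcl11a (1.96), Vrtn (1.93), Zic2 (1.08) and Dnmt3b (0.52) were higher, and Rhox5 (-1.82) and Col4a1 (-0.89) lower. By edgeR, 4221 genes were called, 1910 higher and 2311 lower, and 2811 without N22 DMSO 2.

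N22 against KO22 with DMSO gave 13 of 38 2-cell genes higher and 0 lower (list alone 12). The median was 1.79, or 1.00 with 14 members at their bounds (adjusted p = 0.000881; adjusted p = 0.075 with an estimated correlation), and 0.08 without multi-copy families (adjusted p = 0.791). Lef1 (3.61), Ndufa4l2 (3.55), Aurkc (3.50), Zic2 (2.77) and Lefty1 (1.55) were higher. The secreted protease Htra1 (-3.60), Cemip (-2.96), Nckap1l (-2.54), Wnt6 (-2.36) and Peg10 (-1.51) were lower. By edgeR, 6507 genes were called, 3505 higher and 3002 lower, and 365 of 805 chromosome 6 genes were lower in N22.

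With GSK-3484862, 34 of 38 2-cell genes were lower in KO22 than in WT and 0 higher (list alone 34 and 1), with a median of -8.24, or -5.09 with 21 members at their bounds (adjusted p = 1.18e-36). Fgf1 (-3.75), the oocyte gene Nlrp4a (-2.46) and Gstm2 (-2.39) were lower, as were H19 (-1.46), Lefty1 (-1.26), Xlr3b (-0.89) and Tfap2c (-0.65). Lonrf2 (1.53), Emp1 (1.34), the steroid enzyme Cyp11a1 (1.25) and Dazl, a germ cell RNA-binding protein (0.83), were higher. The X-linked list was lower in 4 of 20 cases and higher in 0 (list alone 4), with a median of -0.38 (adjusted p = 0.0096; adjusted p = 0.147 with an estimated correlation). Trophoblast genes were lower in 4 of 17 cases and higher in 0 (list alone 4; median -0.20, adjusted p = 0.0362; adjusted p = 0.147 with an estimated correlation), a call lost without WT GSK 2 (adjusted p = 0.0916) or KO22 GSK 1 (0.0923). The pluripotency list (10 of 22 higher and 2 lower, list alone 11 and 2; median 0.08, adjusted p = 0.079) passed with no count filter (0.0261) and without chromosome 6 (0.0308). By edgeR, 3728 genes were called, 2044 higher and 1684 lower, and DESeq2 called 2451. Of 805 chromosome 6 genes 313 were higher and 58 lower.

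N22 against WT with GSK-3484862 compares 1 clone, labelled as keeping 1 Dux copy, with WT, so that Dux copy number and clone are not separated. Of 38 2-cell genes 19 were lower, 2 higher and 17 not called (list alone 28 and 5), with a median of -1.11 (adjusted p = 4e-12; adjusted p = 0.0027 with an estimated correlation). Zscan4c was lower by -1.34 ± 0.19, Zscan4d by -1.27 ± 0.18, Zscan4e by -1.30 ± 0.22 and Gm21761 by -0.93 ± 0.13. Tcstv3 (-2.42) lost the call without WT GSK 2 (adjusted p = 0.066), and Usp17la (-0.85) without WT GSK 2 (0.227) or N22 GSK 2 (0.155). Zfp352 (-1.08), Sp110 (-1.70), Tmem92 (-1.59) and Duxf3 (-0.54 ± 0.58; 24 counts against 37) did not pass (adjusted p = 0.123, 0.156, 0.0675 and 0.655). Tmem92 passed without N22 GSK 1 (adjusted p = 0.0236). The X-linked list (-0.13, adjusted p = 0.162) passed without WT GSK 2 (0.033). Summed 2-cell reads were 1.57-fold higher in WT than in N22 with GSK-3484862 and came to 27.3 against 17.0 CPM with DMSO. Without multi-copy families the gap in the sum was not seen, while the list's median was still lower (-0.96, adjusted p = 0.000754). In these sums WT had 58.5 and 54.6 CPM and N22 56.9 and 61.1 with GSK-3484862, and WT had 7.55 and 8.75 and N22 8.57 and 8.65 with DMSO. The sum with DMSO did not separate KO22 (8.68 and 8.43 CPM) from WT either. With GSK-3484862, Ddit4l alone gave 1028 counts in N22, 830 in WT and 750 in KO22. This sum therefore says little about the other single-copy genes. Among the p53 targets 16 of 21 were higher and 0 lower (list alone 17; median 0.20, adjusted p = 1.42e-09), including Trp53inp1 (0.36), Sesn2 (0.30) and Ccng1 (0.28). Primitive endoderm genes were lower in 6 of 18 cases and higher in 0 (list alone 10 and 1), such as Col4a2 (-1.07), Col4a1 (-0.85) and Cubn (-1.08). Their median was -0.47 (adjusted p = 1.31e-06; adjusted p = 0.0667 with an estimated correlation). Gbp9 (1.42), Ephx2 (1.01) and Nfe2 (1.07) were higher, and Slc38a5 (-1.90), Car4 (-1.28), H19 (-0.88) and Peg10 (-0.79) lower. Nfe2 lost the call without any 1 of the 4 libraries (adjusted p = 0.0647 to 0.0971), and Slc38a5 without WT GSK 1 (0.185) or N22 GSK 2 (0.367). By edgeR, 1606 genes were called, 841 higher and 765 lower. DESeq2 called 935, and leaving out WT GSK 1, WT GSK 2, N22 GSK 1 or N22 GSK 2 gave 957, 884, 972 and 960.

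N22 against KO22 with GSK-3484862 gave 33 of 38 2-cell genes higher and 0 lower (list alone 35), with a median of 6.68, or 3.78 with 21 members at their bounds (adjusted p = 4.94e-32). Fgf1 (2.95), Nlrp4a (2.69), Slfn9 (2.20) and Dppa3, a maternal factor that guards methylation in the egg (1.17), were higher. Slc38a5 (-2.50), Rnf128 (-1.72) and Peg10 (-1.53) were lower. Of 21 p53 targets 9 were higher and 0 lower (list alone 13 and 1; median 0.14, adjusted p = 0.000902), with Trp53inp1 at 0.37 and Sesn2 at 0.28. The primitive endoderm list (-0.12, adjusted p = 0.236) passed without N22 GSK 2 (0.0329). By edgeR, 4087 genes were called, 1940 higher and 2147 lower, and 346 of 805 chromosome 6 genes were lower in N22.

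**Figure D3:**
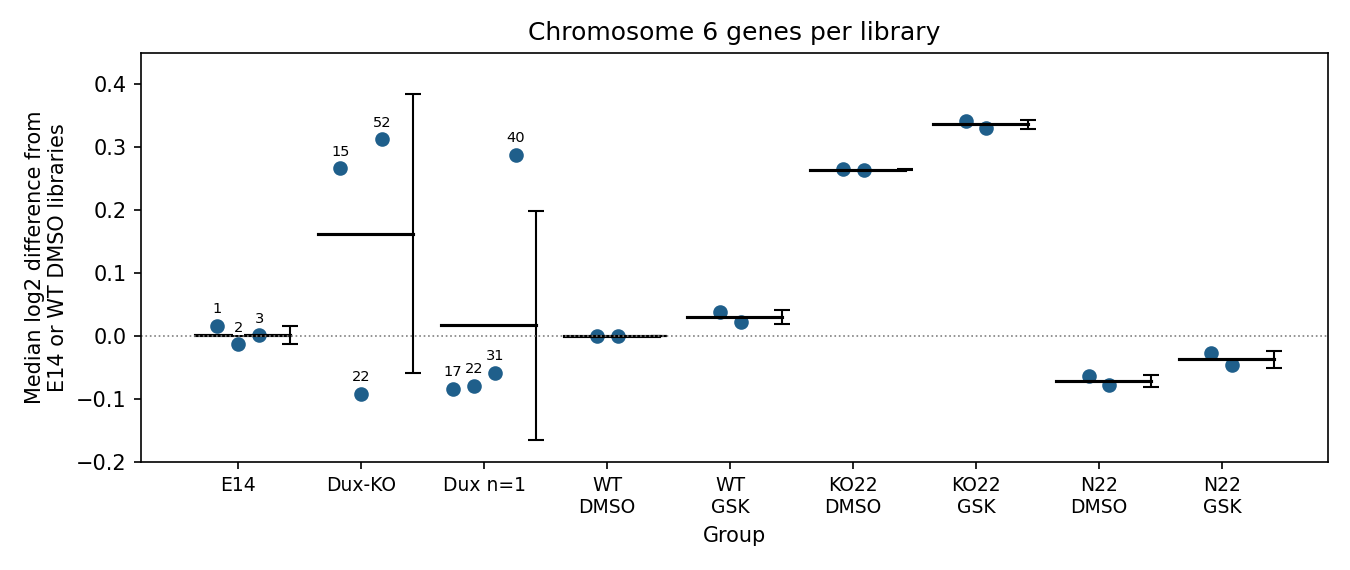
Median log2 difference of chromosome 6 genes from the E14 libraries (untreated set, 689 genes) or the WT DMSO libraries (treated set, 805 genes) for each library (points), with the group mean (line) and SD (bar); clone or replicate numbers stand over the untreated points. Dux-KO clones 15 and 52, Dux n=1 clone 40 and the 4 KO22 libraries sit between 0.26 and 0.34, and the library labelled Dux-KO clone 22 sits at -0.09.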

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

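The chromosome 6 test of the library labelled Dux-KO clone 22 and the GC content tests were chosen only after the results were seen; the other tests were written before, except that 2-cell genes were left out of the label test after its first result.

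Of 24 sets of 4 values tested for a library far from the others, 2 held one, where chance gives about 1 in 20. The chromosome 6 median of Dux n=1 clone 40 was 0.288, against -0.08, -0.08 and -0.06 in the other Dux n=1 clones. Igf2 was at 3.48 CPM in Dux n=1 clone 31, against 2.54, 2.43 and 2.58 CPM.

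The library labelled Dux-KO clone 22 kept more 2-cell reads (26.3 CPM) than the other Dux-KO clones (6.76 and 13.7), with 5 Duxf3 counts. A right label with a stable chromosome 6 level is argued against by its chromosome 6 median of -0.0918, where the KO22 libraries, read as the same clone, lay between 0.26 and 0.34. An exchange of labels with Dux n=1 clone 40 needs that clone to carry more of the difference between KO22 and N22, and over 229 genes off chromosome 6 it did, with a rank correlation across genes of 0.78 against -0.50, a difference of 1.28. The exchange is a candidate explanation, but Dux-KO clone 52 (0.75) lay about as high, so this measure does not single out Dux n=1 clone 40. Dux n=1 clones 17 and 22 lay at -0.59 and -0.76. Dux-KO clone 15 (0.27) and Dux n=1 clone 31 (0.19) lay close together, so it does not clearly separate those clones. Dux n=1 clone 40 also had 5 Zscan4 counts and 1 Duxf3 count, where the KO22 libraries had 0, 0, 0 and 1 Zscan4 counts and 0 Duxf3 counts. Dux-KO clone 15 had 5 Zscan4 counts as well, so counts this low do not decide between the labels. A chromosome 6 change between cultures of 1 clone, another mislabelled sample and clone differences stay open and were not tested.

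The count of genes that differ from E14 may in part follow GC content, whose rank correlation with a library's deviation across genes was -0.59, 0.60 and -0.01 in the 3 E14 libraries and 0.35 to 0.69 in the edited clones. With a GC offset the counts were 973 instead of 3016 for Dux-KO and 328 instead of 1355 for Dux n=1, although most named genes that lost their call kept a similar fold. What share follows GC content cannot be told apart from the clones' own difference, since all edited clones lean 1 way. Every deviation was taken from the same mean of the 3 E14 libraries, so part of this common lean may come from that mean. For Dux n=1 against E14, the real split gave 1355 genes and the highest of the others gave 5 (1 of 35 as large). This share is under 0.05 for this comparison taken alone. It is the smallest the design allows and was not adjusted over the 3 comparisons, so chance is not excluded. For Dux-KO the 10 splits are too few for a share under 0.05 (3016 genes, 1 of 10 as large, highest other 0). An effect of Dux itself stays open and was not tested apart from these.

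Between Dux n=1 and Dux-KO edgeR called 0 genes (856 at an unadjusted p below 0.05, 0 with DESeq2), so all 35 of 35 splits give as many by construction, and their number says nothing about chance. The highest other split gave 1272 genes, with Dux n=1 clones 31 and 40, Dux-KO clone 52 and the library labelled Dux-KO clone 22 on 1 side. It points to a structure of the samples that the groups do not follow, but was picked as the largest and has no reference value. The split follows the GC content trend, at 0.59, 0.55, 0.58 and 0.69 on that side. Dux-KO clone 15 and Dux n=1 clones 17 and 22 had 0.47, 0.50 and 0.35. Whether GC content accounts for the split was not tested.

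Responses to GSK-3484862 that differed between genotypes by the interaction test are given as values. KO22 differed from WT in 5286 genes and in the 2-cell list (median -3.25). N22 differed from WT in 1844 genes and in the imprinted (0.20), DNA methylation machinery (-0.11), primed and germ layer (-0.30) and p53 (0.33) lists, the first 3 of which no longer passed with an estimated correlation (adjusted p = 0.0771 each). N22 differed from KO22 in 3101 genes and in the 2-cell (3.05), primed and germ layer (-0.39) and p53 (0.35) lists. That primed and germ layer call was lost with an estimated correlation (adjusted p = 0.143), with a GC offset (0.119), with no count filter (0.192) and without any 1 KO22 or N22 library (0.128 to 0.245).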

How the results depend on the processing

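The GC content offset, the omission of 2 doubted libraries and the omission of chromosome 6 were chosen only after the results were seen. Unless stated, the cause of a change was not tested.

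Gene counts stayed within 1.5 times in 28 of 41 alternatives for the untreated set and 135 of 144 for the treated set. The GC offset gave 973 (Dux-KO against E14) and 328 (Dux n=1 against E14). DESeq2 gave 2515 (Dux n=1 against E14), 1178 (response of N22 minus WT), 2047 (N22 minus KO22), 2451 (KO22 against WT with GSK-3484862) and 935 (N22 against WT with GSK-3484862). Only the compared groups in the fit gave 2450 for Dux n=1 against E14. Without 1 library, counts ran from 931 to 3572 for Dux-KO against E14 (E14 library 1 931, 2 1739, 3 1171, Dux-KO clone 15 1977) and from 24 to 1237 for Dux n=1 against E14 (E14 library 1 24, 2 344, 3 52, Dux n=1 clone 17 351). They ran from 2811 (without N22 DMSO 2) to 3048 for N22 against WT with DMSO, and from 884 to 972 with GSK-3484862 (WT GSK 1 957, WT GSK 2 884, N22 GSK 1 972, N22 GSK 2 960). Fewer libraries were tested in each omission. Which direction held more genes also changed with the setting. N22 against WT with DMSO gave 2127 higher and 1806 lower with no count filter, and 1616 and 1416 with DESeq2. The N22 minus WT response gave 767 and 975, and 531 and 647, in these settings. With no count filter, GSK-3484862 gave 3723 and 3961 in KO22 and 4245 and 4470 in N22. KO22 against WT with DMSO then gave 4234 and 4132. RLE factors gave 2110 higher and 2077 lower for N22 against WT with DMSO, and 858 and 975 for the N22 minus WT response. They gave 2051 and 2012 for N22 against KO22 with GSK-3484862. With the library labelled Dux-KO clone 22 and Dux n=1 clone 40 left out, Dux n=1 against Dux-KO gave 140 genes, a 2-cell median of 0.74 and Usp17la at 0.25.

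The 2-cell list kept its direction and side of the threshold in 33 of 41 and 139 of 144 alternatives. With an estimated correlation, medians of -1.64, -1.78 (Dux-KO and Dux n=1 against E14) and 1.79 (N22 against KO22 with DMSO) no longer passed. Without multi-copy families, which leaves fewer genes, neither did -0.47, -0.68, -2.72 (KO22 against WT with DMSO), -1.40 (N22 against WT with DMSO) and 0.0791 (N22 against KO22 with DMSO), and summed 2-cell log2 CPM differed by -0.80 (Dux n=1 minus E14) and -0.0575 (Dux n=1 minus Dux-KO, where all libraries gave a value above 0). Omissions moved Dux n=1 against Dux-KO from -0.65 (passing, without Dux-KO clone 15) to 0.52 (without the library labelled Dux-KO clone 22; 0.08 without Dux n=1 clone 40), and its summed CPM difference from -0.49 to 0.49 without the same 2 Dux-KO libraries, and below 0 without Dux n=1 clone 17 (-0.05) or 22 (-0.12). The N22 minus WT response ran from -0.0139 (without WT DMSO 2) to 0.61.

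Named genes, called or not, kept their direction and side of the threshold in 412 of 554 untreated and 1861 of 1885 treated alternatives, with 129 and 19 weaker, 4 and 2 stronger, and 9 and 3 reversed. In Dux n=1 against Dux-KO, omissions took Zscan4c from -0.28 to 1.85, Zscan4d from -0.30 to 0.61 (both below 0 without Dux-KO clone 15 or Dux n=1 clone 17 or 22) and Usp17la from -1.04 to 0.0403 (above 0 without Dux n=1 clone 31 or 40). Zscan4d in N22 minus WT ran from -0.56 to 1.37 (below 0 without N22 DMSO 1, WT DMSO 2 or N22 GSK 2). Other lists kept their side of the threshold in 1794 of 1907 alternatives, although 128 medians called in neither setting changed sign, and 20 of 40 camera calls were lost with an estimated correlation.

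The treated libraries share only a number: over 15 group pairs, deviations of same-numbered libraries correlated across genes at -0.03 to 0.14. With a replicate block, 12 of 12 gene counts stayed within 1.5 times (9459 for GSK-3484862 in WT), and 12 of 12 2-cell results and 217 of 218 named genes, called or not, kept their side of the threshold; Tmem92 passed (N22 against WT with GSK-3484862, -1.63, adjusted p = 0.0393) and the primed and germ layer list no longer did (N22 minus KO22, adjusted p = 0.052).

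At this depth Duxf3 had at most 5 counts in any untreated library, which limits what can be said of Dux there.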

Other observations

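The test of whether imprinted genes were lost from the genome was chosen only after the result was seen; the test over the untreated clones was written before.

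Genes of the imprinted region on chromosome 12 differed between lines with DMSO alone. With DMSO, Mirg had 46 counts in WT and 0 in KO22 and in N22, and Rtl1 had 10, 0 and 0, while with GSK-3484862 Mirg had 717, 657 and 610 counts and Rtl1 191, 148 and 133. The untreated E14 libraries held Meg3 at 0.447 ± 0.048 CPM (SD, n = 3), against 15.0 ± 1.19 CPM in WT with DMSO (SD, n = 2), and no test was run between these sets.

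Meg3 (chromosome 12, 109541001 to 109571726), Rian, Mirg and Rtl1 were near 0 in KO22 and N22 with DMSO. Loss of the genes from the genome is argued against, since the lower of the 2 Meg3 means with GSK-3484862 was 133 CPM. The same low state in each untreated edited clone was found, with a highest Meg3 level of 0.484 CPM. Unedited E14 was low too (mean 0.447 CPM), above the means of Dux-KO (0.0347) and Dux n=1 (0.189) and below WT with DMSO. The test therefore cannot tell a state of edited clones from that of E14, and what editing adds stays open. Methylation of the region may account for the low state in these lines, as a hypothesis; DNA methylation was not analysed here, and passage history stays open.

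The small RNA Rn7sk was uneven between libraries of 1 group elsewhere too, at 7.48 CPM in N22 DMSO 1 and 0.369 in N22 DMSO 2.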
